A study of Homo sapiens with 2 samples.

How the data were processed

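RNA from lung microvascular endothelial cells of human origin was purified with a Zymo kit and a DNase I step, and sequenced on an Illumina HiSeq instrument by a service provider, per the labels' protocols. Of the 2 libraries, 1 came from cells overexpressing GFP and 1 from cells overexpressing TMEM100, so each group has 1 library. How the genes were delivered, and whether the cultures shared a donor, is not given in the sources used here.

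Reads were processed with HISAT2 and Cuffdiff, per the submitters' processing notes; their versions, the genome build and the annotation are not given in the sources used here. The values used are FPKM as deposited, the output of the authors' Cuffdiff run, with 1 column per library and 60653 rows with Ensembl gene identifiers. Columns were assigned to libraries from the sample names that the table's header fields pair with them. The p-value and q-value of each row come from the authors' own comparison of the libraries, per the file headers. The score in the deposited table is the authors' Cuffdiff test statistic, which was not used further. The authors' column of log2 fold changes was not used, because part of its cells hold spreadsheet error text. A further 3 gene symbols had been turned into dates by a spreadsheet and were restored from the Ensembl identifiers. Of the identifiers, 99.5% were found in a table of gene names and 96.4% in GENCODE 29. The deposited loci enclosed the GENCODE 29 gene in GRCh38 coordinates for 92.3% of the shared identifiers and equalled it for 34.5%, so coordinates printed here are those of GENCODE 29.

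Rows that share a symbol were summed (68 rows). Differences were computed as log2(FPKM + 1) in the TMEM100 library minus log2(FPKM + 1) in the GFP library, a scale that understates the change of low genes. Genes with a mean of at least 1 FPKM were compared (12036), which left out 39264 rows at 0 in both libraries and the other low rows. With 1 library per group there is no test: genes were counted at a difference of at least 2-fold on this scale, and members of lists at 1.5-fold. For each gene list, the median difference of its members above the minimum was set against 10000 random lists of the same size, each member replaced by 1 of its 100 nearest genes in mean expression. A list stood apart if its median lay in the outermost 2.5% at either end. The percentile describes these libraries and is not a p-value.

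The FPKM values carry depth only indirectly. In low genes (a mean under 0.5 FPKM) the ratio of the libraries' values should be a ratio of small whole numbers times a constant. Of 4255 such genes, 30.5% lay within 0.001 (log2) of a ratio of whole numbers up to 5 at the best constant, against a median of 0.47% at other offsets, which gives the relative depth of 103.7%. The absolute depth is an estimate that assumes GENCODE 29 lengths and 200 nt fragments. It rests on the median over 163 genes with a single transcript of 1000 to 6000 nt, and is 43.5 fragments for a 2 kb transcript at 1 FPKM in the GFP library, with quartiles of 21.9 and 43.9 over those genes. No interval was computed from it.

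Chosen before the data were examined were the groups, the pseudocount, the minimum, the thresholds, the 30 gene lists, most alternatives and the rule for named genes. That rule takes TMEM100, then the 15 highest and 15 lowest differences among symbols with at least 5 FPKM in a library. It leaves out XIST, Y-linked genes, rows that merge several genes, and small RNAs as far as the start of their symbol shows them, so short RNAs with clone-based names stay in. From each list that stands apart it adds up to 4 members with the largest differences, and it does so in any case for the pan-endothelial, lung capillary, arterial and Notch, BMP, junction and interferon lists. Not every gene that the rule takes is reported here. Other genes named here were chosen after their values were seen, as were 6 further gene lists in the closing section and the alternatives that use only protein-coding genes, leave out overlapping genes, or remove trends with GC content and transcript length. The alternatives set beforehand were pseudocounts of 0.1 and 5, no minimum or a minimum of 5 FPKM, TPM, the median log2 ratio set to 0, the highest row per symbol, only rows the authors tested, unmatched random lists, the mean in place of the median, and a q-value of 0.01 in the authors' deposited table.

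The calculations were tested on simulated data for this comparison: fragments were drawn for 12003 genes at the estimated depth, with 200 genes altered, 50 at each of 4 sizes, and a list of 20 genes raised 1.5-fold. Among altered genes of at least 5 FPKM, 100% of 35 at 3-fold, 33 at 4-fold and 32 at 6-fold and 0% of 30 at 1.5-fold passed 2-fold in the right direction. Of the unaltered genes, 0.085% passed 2-fold. The simulation held counting noise alone, without variation between cultures, so its rates are not error rates for the real libraries. The planted list lay at percentile 100, and 9% of 100 unaltered lists stood apart. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 for overlaps of exons.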

Results

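Gene expression was measured by RNA sequencing in human pulmonary microvascular endothelial cells, the primary cells that line the smallest vessels of the lung. The cells overexpressed either TMEM100, a small transmembrane protein that is enriched in lung endothelium, or green fluorescent protein (GFP) as the control. There was 1 library per group and 2 in all, so no difference here has a replicate check and no p-value was computed. The values are FPKM (fragments per kilobase of transcript, scaled to library size), and their totals were 803084 in the GFP library and 803062 in the TMEM100 library. From the FPKM worth of 1 fragment, the depth of the TMEM100 library was estimated at 103.7% of that of the GFP library. This is the depth by which the values were scaled, which need not equal the ratio of all fragments. A gene with a 2 kb transcript at 1 FPKM was thus backed by an estimated 43.5 fragments in the GFP library and 45.1 in the TMEM100 library. The series compares these cells to ask what TMEM100 overexpression does to gene expression in lung endothelium.

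TMEM100 itself was listed at 0 FPKM in the GFP library and at 21.9 FPKM in the TMEM100 library. The gene (ENSG00000166292) lies on the minus strand of chromosome 17, from 55719627 to 55732121 in GRCh38, per GENCODE 29. Its difference on the log2(FPKM + 1) scale was 4.52. No fold is given, because the gene is listed at 0 in the control. In the authors' deposited table TMEM100 had p = 5e-05 and q = 0.0373.

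In the TMEM100 library genes of the cell cycle were higher, while venous, lymphatic and tip cell genes were lower than in the GFP library. Of 12036 genes with a mean of at least 1 FPKM, 134 were at least 2-fold higher in the TMEM100 library and 204 at least 2-fold lower, on the log2(FPKM + 1) scale. Protein-coding genes made up 90 of the 134 and 137 of the 204. The median difference over the 12036 genes was 0.01, and the 5th and 95th percentiles were -0.65 and 0.63. Pearson's r between the libraries was 0.976 across genes, which are not independent replicates. Of 30 gene lists, 7 had a median in the highest 2.5% and 10 in the lowest 2.5% of 10000 random lists matched on expression. If genes varied independently, 1.5 lists would pass by chance, although 9% of 100 unaltered lists stood apart in the simulated libraries. Genes of a list vary together, so the random lists understate what chance can give.

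**Figure D1:**
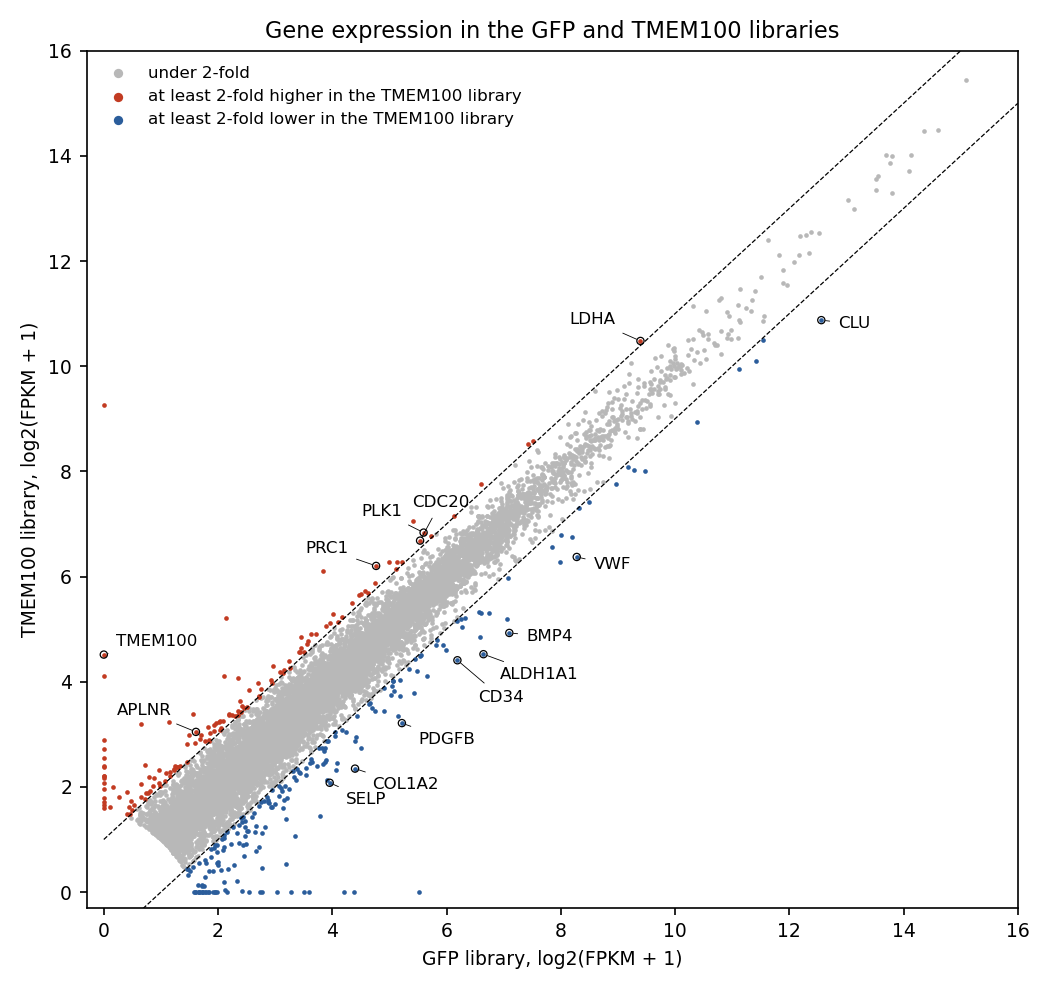
Expression of each gene in the GFP library (horizontal axis) and the TMEM100 library (vertical axis), both as log2(FPKM + 1), for the 12036 genes with a mean of at least 1 FPKM, without XIST and Y-linked genes. Dashed lines mark a difference of 2-fold; TMEM100 lies on the vertical axis at 0 FPKM in the GFP library and 21.9 in the TMEM100 library, PLK1 lies above the upper line and CLU, VWF and BMP4 lie below the lower line.

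Cell cycle genes were higher in the TMEM100 library throughout both lists. All 24 measured genes of the G2 and M phases had higher values in the TMEM100 library, 22 of them at least 1.5-fold, and the list's median difference was 0.97 (percentile 100 of the random lists). PLK1, a kinase that drives entry into mitosis, was at 47.5 FPKM in the GFP library and 113 FPKM in the TMEM100 library. The proliferation marker MKI67 was at 8.43 and 20.04 FPKM, HMMR at 3.07 and 8.48 FPKM, and AURKB, the kinase of the chromosomal passenger complex, at 14.6 and 33.8 FPKM. All 23 measured genes of the S phase list were likewise higher, 17 of them at least 1.5-fold, with a median difference of 0.87 (percentile 100). RRM2, a subunit of the enzyme that makes deoxyribonucleotides, was at 21.8 and 49.99 FPKM, and the transcription factor E2F1 at 3.91 and 9.16 FPKM. CLSPN was at 1.45 and 4.21 FPKM, and CDC45, part of the replicative helicase, at 4.08 and 9.34 FPKM. Of 12 replication-dependent histone genes, the 4 above the minimum had a median difference of -0.25 (percentile 8.38), and none differed by 1.5-fold. Their transcripts lack a poly(A) tail, so their values also depend on how RNA was selected and do not decide on S phase. Targets of p53 had a median of -0.08 (percentile 7.62), with 0 of 22 members past 1.5-fold; CDKN1A, the cell cycle inhibitor among them, was at 414 and 404 FPKM.

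Venous and general endothelial genes were lower in the TMEM100 library. VWF, which encodes von Willebrand factor, was at 310 FPKM in the GFP library and 81.9 FPKM in the TMEM100 library, and CD34 at 72.0 and 20.2 FPKM. SELP, the adhesion receptor P-selectin, was at 14.5 and 3.22 FPKM. The venous list had a median difference of -0.58 (percentile 0), with 4 of 9 members at least 1.5-fold lower and 1 higher. The member that was higher was APLNR, the apelin receptor, at 2.06 and 7.26 FPKM; NR2F2, a transcription factor of venous identity, was at 162 and 153 FPKM. The pan-endothelial list had a median of -0.30 (percentile 0.01), with 5 of 20 members at least 1.5-fold lower and none higher. PLVAP was at 9.72 and 3.90 FPKM and EMCN at 86.0 and 51.5 FPKM, while CDH5 (VE-cadherin) was at 366 and 312 FPKM and NOS3 at 81.1 and 117 FPKM. The lymphatic list had a median of -0.60 (percentile 0), and 4 of 7 members were at least 1.5-fold lower: MMRN1 (501 and 216 FPKM), TBX1 (15.6 and 7.30), FLT4 (20.9 and 10.9) and RELN (1.70 and 0.776). VWF and PLVAP are on both the venous and the pan-endothelial lists, and FLT4 is on both the venous and the lymphatic lists. PROX1, the transcription factor of lymphatic identity, was at 0.609 and 0.611 FPKM.

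Tip cell, junction and arterial genes were also lower as groups. The tip cell and angiogenesis list had a median difference of -0.46 (percentile 0), with 7 of 17 members at least 1.5-fold lower and 1 higher. PDGFB, the growth factor that recruits pericytes, was at 36.2 and 8.27 FPKM, and the type IV collagen chains COL4A1 and COL4A2 were at 361 and 169 FPKM and at 428 and 222 FPKM. VEGFC was the member at least 1.5-fold higher, at 16.9 and 31.2 FPKM. Differences were below 0 for 11 of the 17 members and above 0 for 6, among them ESM1 at 29.9 and 39.2 FPKM. The junction and barrier list had a median of -0.22 (percentile 0.1), with 6 of 22 members at least 1.5-fold lower and none higher. JUP (plakoglobin) was at 291 and 107 FPKM, OCLN (occludin) at 1.60 and 0.402 FPKM, ANGPT2 at 21.6 and 11.4 FPKM and PTPRB at 22.1 and 11.8 FPKM. The arterial and Notch list had a median of -0.18 (percentile 1.25), with 3 of 19 members at least 1.5-fold lower and 1 higher. The Notch ligand DLL4 was at 7.02 and 3.86 FPKM, NRARP at 23.6 and 12.4 FPKM and CXCR4 at 1.802 and 0.450 FPKM, whereas the Notch target HEY2 was at 4.49 and 10.3 FPKM. These lists share members: CXCR4 and DLL4 are also on the tip cell list, ANGPT2 is on the tip cell and junction lists, and PECAM1, at least 1.5-fold lower, is on the junction and pan-endothelial lists. Only 10 of the 24 lung capillary genes were above the minimum, and some, such as HPGD, SOSTDC1 and TBX2, were listed at 0 in both libraries. Those above it went both ways: the median was 0.15 (percentile 88.3) and the mean -0.13, with 2 of 10 members at least 1.5-fold higher and 3 lower. CD36 was at 2.99 and 0.435 FPKM, TMEM204 at 9.26 and 4.56 FPKM and RAMP2 at 397 and 221 FPKM, against 2.96 and 5.72 FPKM for FOXF1.

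**Figure D2:**
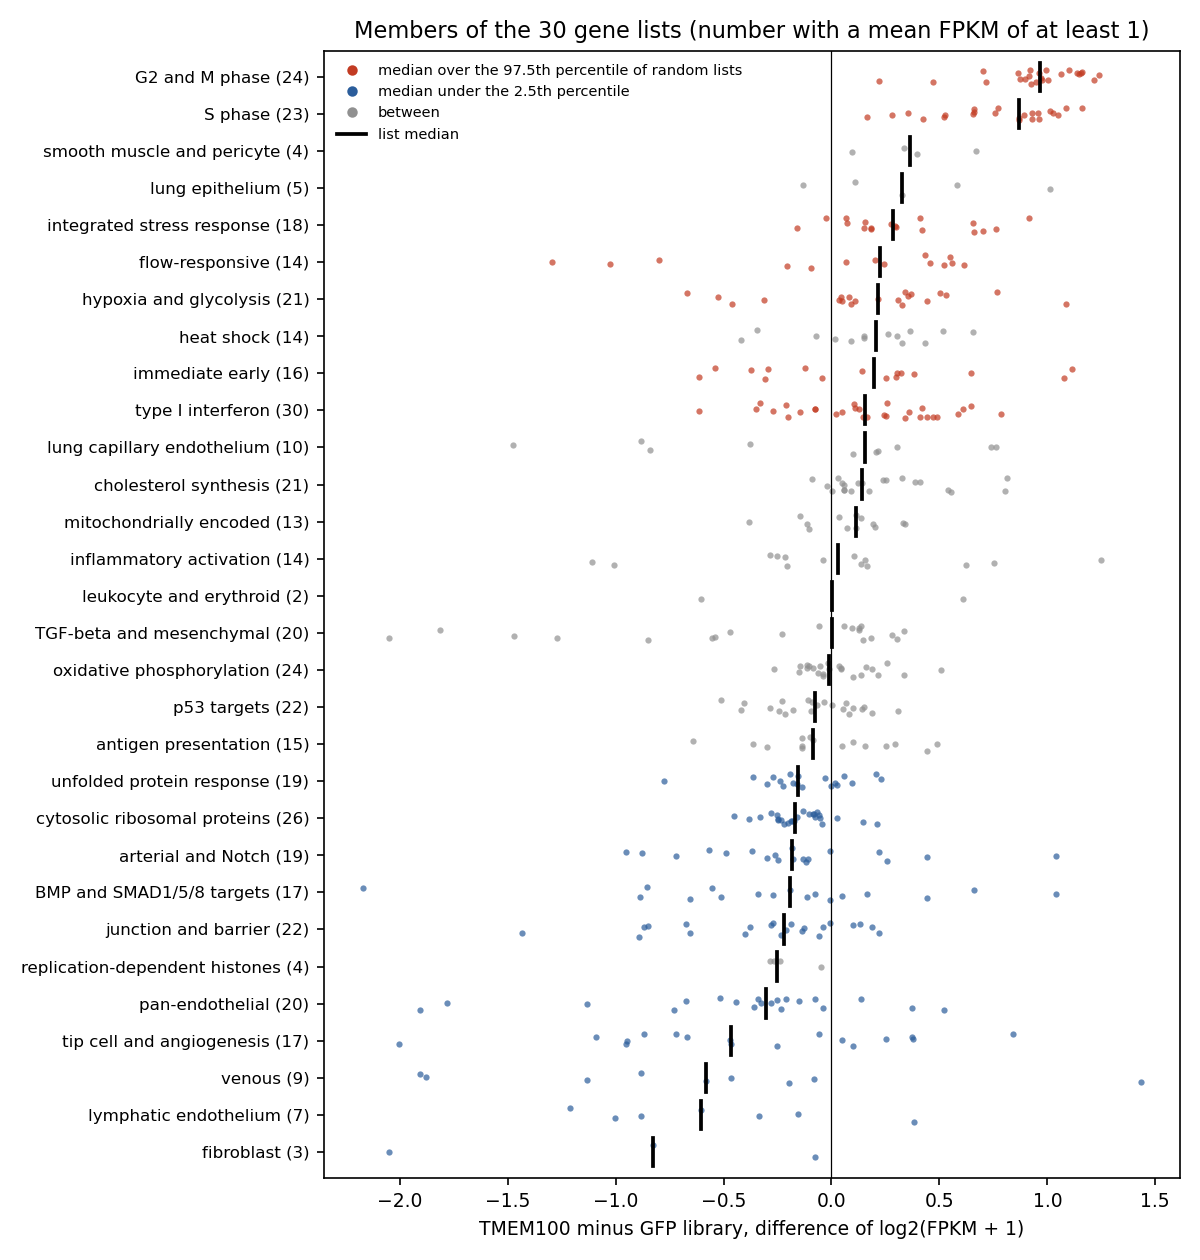
Differences between the TMEM100 and GFP libraries, as log2(FPKM + 1), for the members of the 30 gene lists; each point is a gene with a mean of at least 1 FPKM, the number of such genes follows each list's name, and the black bar is the list's median. Colours mark medians in the outermost 2.5% at either end of the matched random lists; the members of the G2 and M list lie above 0 in 24 of 24 cases and those of the S phase list in 23 of 23.

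The list of bone morphogenetic protein (BMP) signalling, in which TMEM100 is known to take part, had a median below 0 but was divided. It holds ligands and receptors of the pathway as well as its targets, so its median does not describe the targets alone. The list's median was -0.19 (percentile 1.17), with 4 of 17 members at least 1.5-fold lower and 2 higher. The ligands BMP4 and BMP2 were at 136 and 29.4 FPKM and at 17.4 and 10.7 FPKM. ATOH8 was at 17.3 and 8.89 FPKM and ID2 at 8.45 and 4.22 FPKM. HEY2 and SMAD9 were the members at least 1.5-fold higher, SMAD9 at 3.63 and 6.33 FPKM. The direct target ID1 was at 109 and 123 FPKM and ID3 at 355 and 248 FPKM. With a pseudocount of 5, without a minimum, or without genes whose exons overlap another gene, the median was -0.11 and no longer stood apart. Genes of transforming growth factor beta signalling and mesenchymal identity had a median of 0.00 (percentile 51.5) but a mean of -0.38, since 5 of 20 members were at least 1.5-fold lower and none higher. Those 5 were COL1A2 (20.1 and 4.09 FPKM), POSTN (34.7 and 9.13), CCN2 (709 and 255), MMP2 (625 and 258) and TGFB2 (7.24 and 3.57), while ACTA2 was at 31.5 and 33.8 FPKM.

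The integrated stress response list and the hypoxia and glycolysis list had medians above 0, with few members past 1.5-fold. The integrated stress response list had a median of 0.28 (percentile 99.8), with 5 of 18 members at least 1.5-fold higher and none lower. These were the amino acid transporters SLC7A5 (5.92 and 12.1 FPKM) and SLC7A11 (2.22 and 4.07), the serine synthesis enzymes PSAT1 (5.92 and 10.3) and PHGDH (1.78 and 3.39), and STC2 (3.67 and 6.90). ATF4, the transcription factor of this response, was at 120 and 118 FPKM. The hypoxia and glycolysis list had a median of 0.22 (percentile 99.7), with 2 of 21 members at least 1.5-fold higher and 1 lower. LDHA (lactate dehydrogenase A) was at 672 and 1428 FPKM and HK2 (hexokinase 2) at 1.87 and 3.88 FPKM, whereas the hypoxia-induced peptide ADM was at 38.3 and 23.7 FPKM and VEGFA at 2.84 and 2.96 FPKM. The median of the unfolded protein response list was -0.16 (percentile 1.11), and 1 of 19 members, DNAJB9, was at least 1.5-fold lower, at 22.99 and 13.03 FPKM. Cytosolic ribosomal proteins had a median of -0.17 (percentile 2.45), with 23 of 26 members lower and none past 1.5-fold. Of 13 alternative settings, the hypoxia list no longer stood apart in 3 (medians of 0.10, 0.11 and 0.08) and the integrated stress list in 1 (0.19). The unfolded protein response list no longer stood apart in 3 (-0.16, -0.13 and -0.14) and the ribosomal protein list in 2 (-0.15 and -0.18).

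Interferon, flow-responsive and immediate early genes had medians above those of the random lists by small amounts. The type I interferon list had a median of 0.15 (percentile 98.3), with 4 of 30 members at least 1.5-fold higher and 1 lower. OAS3 was at 6.57 and 12.1 FPKM, IFI35 at 16.8 and 27.0 FPKM and MX1 at 8.45 and 13.4 FPKM. Flow-responsive genes had a median of 0.22 (percentile 99.0) and a mean of 0.02, with 1 of 14 members at least 1.5-fold higher and 3 lower. PLAT, the tissue plasminogen activator, was at 177 and 272 FPKM, while the vasoconstrictor EDN1 was at 230 and 93.4 FPKM, TFPI at 320 and 157 FPKM and ASS1 at 19.6 and 10.8 FPKM. The members were not sorted by whether flow raises or lowers them, so the median and mean give no direction of a flow response. Immediate early genes had a median of 0.20 (percentile 97.8), with 3 of 16 members at least 1.5-fold higher and 1 lower. DUSP5 was at 5.76 and 13.6 FPKM, FOSL1 at 181 and 384 FPKM and ZFP36 at 11.99 and 19.4 FPKM, against 289 and 188 FPKM for IER3. The immediate early list no longer stood apart in 7 of the 13 alternative settings, and its median was -0.02 without a minimum, so its direction is not settled. The interferon list no longer stood apart in 1 setting (0.17) and the flow-responsive list in 2 (0.13, and 0.02 for the mean).

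Several groups did not stand apart from the random lists. Inflammatory genes had a median of 0.03 (percentile 54.9), with CSF3 at 2.81 and 8.05 FPKM and ICAM1 at 39.8 and 17.9 FPKM. The medians were -0.09 for antigen presentation (percentile 13.1), 0.21 for heat shock (percentile 95.7), 0.14 for cholesterol synthesis (percentile 89.96), -0.01 for nuclear genes of oxidative phosphorylation (percentile 26.8) and 0.11 for mitochondrially encoded genes (percentile 92.7). Mitochondrially encoded genes took 27.4% of the FPKM total in the GFP library and 28.3% in the TMEM100 library.

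Markers of other cell types were mostly under the minimum of 1 FPKM. The fibroblast list had a median of -0.82 (percentile 0.17) over only 3 of its 14 members, COL1A2, COL6A1 (36.8 and 20.3 FPKM) and LOXL1 (7.08 and 6.66 FPKM), of which COL1A2 is also on the mesenchymal list; without a minimum it was -0.09 and did not stand apart. Other abundant fibroblast transcripts were low in both libraries and went both ways. COL1A1 was at 0.224 and 0.268 FPKM and DCN at 0.119 and 0.125 FPKM, while COL3A1 was at 1.34 and 0.616 FPKM and LUM at 0.517 and 0.217 FPKM. The median was 0.37 for 4 smooth muscle and pericyte genes (percentile 96.8), 0.33 for 5 lung epithelial genes (percentile 96.0) and 0.00 for 2 leukocyte and erythroid genes (percentile 46.3). RGS5 was at 583 and 929 FPKM and the keratin KRT19 at 69.3 and 141 FPKM, while the leukocyte gene PTPRC and the alveolar epithelial gene SFTPC were listed at 0 in both libraries.

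The protein-coding genes with the largest differences outside the 30 lists included ALDH1A1, a retinaldehyde dehydrogenase, at 99.2 and 22.003 FPKM, and NTN4 (netrin 4) at 94.8 and 28.0 FPKM. The mitotic spindle protein PRC1 was at 26.2 and 72.6 FPKM and PCLAF, a partner of the replication clamp, at 9.98 and 27.9 FPKM. Leaving out TMEM100, among the 15 highest and 15 lowest differences at 5 FPKM or more, 8 of the 15 at each end were not protein-coding. Exons overlapped another gene in 11 of the 15 highest and 8 of the 15 lowest. The highest was AC004079.1, a short non-coding RNA listed at 0 and 613 FPKM, and the lowest was AC022966.2, an antisense RNA at 45.0 FPKM and listed at 0. The next highest, LUZP6, was at 3.42 and 36.2 FPKM and shares its exons with MTPN. Values of overlapping genes are uncertain, because the sources used here do not say whether fragments were counted by strand.

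The authors' deposited table compares the same libraries, not the conditions, with Cuffdiff. It tested 14187 rows and marked 19 at q under 0.05, of which 18 were lower in the TMEM100 library and 1, TMEM100, was higher. All 19 had the same q of 0.0373 in the authors' deposited table, at the lowest p that it holds, 5e-05. The 18 lower rows in the authors' deposited table were ADGRA2, ELN, SNCAIP, VASH1, NTN4, NUAK1, PDGFB, TFPI2, SLC30A3, BMP4, GALNT15, POSTN, COL1A2, ALDH1A1, CD34, PDE4B, CCL14 and the non-coding AC022784.1. CCL14, a chemokine, was at 253 and 76.4 FPKM, TFPI2, an inhibitor of serine proteases, at 132 and 35.6 FPKM, and ELN (elastin) at 16.04 and 4.45 FPKM. At an unadjusted p under 0.05, the authors' deposited table held 301 lower and 260 higher rows. PLK1 had p = 0.00245 and q = 0.419 in the authors' deposited table, and VWF p = 0.0003 and q = 0.137.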

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

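The alternatives that use protein-coding genes alone, leave out overlapping genes or remove GC and length trends were chosen after the data were seen. Of the 30 lists, 18 kept their call, apart or not, in every setting run, but some that did not stand apart changed sign. Among the lists that stood apart, direction and call were both kept by both cell cycle lists and the venous, lymphatic, pan-endothelial, tip cell, junction, and arterial and Notch lists. Of 924 values of named genes, 40 moved and 0 reversed. A reversal was counted only for genes that differed at least 2-fold, and most settings cannot change a gene's sign. The 0 is therefore no evidence of stability. The causes of the list changes below were not tested. Pseudocount 0.1 gave 289 genes at least 2-fold higher and 388 lower, a TMEM100 level difference of 7.78, and medians of 0.17 for interferon and 0.20 for immediate early genes, which no longer stood apart, and 0.53 for lung epithelium, which now did. Pseudocount 5 gave 31 and 61 genes, a TMEM100 level difference of 2.43, and lost the BMP (-0.11) and hypoxia (0.10) lists; the counts move because a pseudocount compresses low genes. Without a minimum, the BMP (-0.11), integrated stress (0.19), hypoxia (0.11) and fibroblast (-0.086) lists were lost and the immediate early median reversed to -0.023. A minimum of 5 FPKM left 74 and 104 genes, from fewer genes compared, and brought in lung epithelium (0.58). TPM multiplies both libraries by nearly the same factor, so it acts through the pseudocount and minimum alone; the immediate early list (0.14) was lost and TMEM100 differed by 4.82. With the median ratio set to 0, immediate early genes (0.17) were lost, as they were with GC and length trends removed (0.20). Against unmatched random lists, the unfolded protein response (-0.16) and immediate early (0.20) lists were lost. With means, flow-responsive (0.016), unfolded protein response (-0.13), ribosomal protein (-0.15) and immediate early (0.14) lists were lost, and TGF-beta (-0.38) and cholesterol (0.24) lists stood apart. Without overlapping genes, 63 and 94 genes were past 2-fold, the smooth muscle list gave no value, the BMP (-0.11), flow-responsive (0.13), unfolded protein response (-0.14), hypoxia (0.076) and ribosomal protein (-0.18) lists were lost, and TGF-beta (-0.35) and lung epithelium (0.56) stood apart. At q under 0.01 the authors' deposited Cuffdiff table holds 0 rows, against 19 at 0.05 and 561 at an unadjusted p under 0.05.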

Other observations

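The 6 gene lists in this part were chosen after the data were seen, some because members were already known to differ, so their medians describe those genes and do not test the groups. Cargo of the Weibel-Palade bodies, the endothelial storage granules, had a median difference of -0.72 over 8 genes; VWF, SELP, EDN1 and ANGPT2, seen to be low before the list was made, were the 4 at least 1.5-fold lower, and IGFBP7 was at 666 and 448 FPKM. Basement membrane genes had a median of -0.43 over 16 genes, with 6 at least 1.5-fold lower: NID1 (nidogen 1) was at 76.1 and 31.9 FPKM and LAMB2 at 220 and 122 FPKM, while LAMA5 was higher, at 31.1 and 60.1 FPKM. All 7 measured GIMAP genes, a family of GTPases encoded together, were lower, with a median of -0.69 and GIMAP7 at 79.1 and 35.9 FPKM. All 20 genes of ribosome biogenesis were higher, with a median of 0.42 and 5 at least 1.5-fold higher; NCL (nucleolin) was at 168 and 254 FPKM and DKC1 at 10.2 and 17.3 FPKM. Keratins of simple epithelia had a median of 0.76 over 5 genes, with KRT7 at 146 and 279 FPKM and KRT8 at 24.5 and 22.3 FPKM. Of 95 genes with a mean of at least 1000 FPKM, 7 were at least 1.5-fold lower and 3 higher. The lower ones included CLU (6042 and 1879 FPKM), MGP (2719 and 1095), EFEMP1 (2976 and 1441) and THBS1 (2212 and 986), and the higher ones were LDHA, HMGA1 (1280 and 2275) and the metallothionein MT2A (3168 and 5417).

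Of the tests below, those of YAP targets, other culture differences, fibroblasts and lymphatic cells were chosen after the values were seen, and the pattern of non-coding rows was defined after its overlap test. The removal of GC and length trends was likewise chosen after the data were seen. The patterns themselves were taken from these data. The 47 cell cycle genes had a joint median difference of 0.92. Removing trends with GC content and transcript length left it at 0.918, and the highest median in 1000 simulated pairs with counting noise alone was 0.0667, which argues against both as the cause. A sparser culture could raise proliferation and the targets of the density sensor YAP. The 19 YAP targets had a median of 0.01, with a bootstrapped interval of -0.35 to 0.308. That interval resamples genes, which are not independent, so it describes spread among them and not between cultures. Members such as AXL (55.5 and 112 FPKM) and CCN2 (709 and 255 FPKM) went opposite ways, so density stays open. With 1 library per group, a difference between the cultures other than the transgene cannot be told apart from an effect of TMEM100, and both remain possible.

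The 67 genes of the pan-endothelial, venous, lymphatic, tip cell, junction and fibroblast lists had a joint median of -0.34. Each of these lists had stood apart as lower in these libraries, so the joint median is low by choice. Other lists that stood apart as lower were not pooled. Their medians were -0.18 (arterial and Notch), -0.19 (BMP), -0.16 (unfolded protein response) and -0.17 (ribosomal proteins). The joint median was -0.313 with GC and length trends removed. The lowest median of the same genes in 1000 simulated pairs with counting noise alone was -0.0182, but no genes were chosen for being low in those pairs. Fewer fibroblasts in the TMEM100 library would need their other abundant transcripts in the GFP library. COL3A1 and LUM were lower in the TMEM100 library and COL1A1 and DCN were not, yet the median of COL1A1, COL3A1, DCN and LUM in the GFP library was 1.84% of COL1A2. Likewise, the highest of the lymphatic markers PROX1, PDPN and CCL21 was 0.122% of MMRN1, which argues against a loss of lymphatic cells as the whole cause, although LYVE1 of the same list was at 138 and 109 FPKM. A response to TMEM100, a byproduct of faster proliferation, if there was any, or another difference between the cultures may underlie the pattern. These were not tested, and growth of the cultures is not given in the sources used here.

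Non-coding rows passed 2-fold more often than protein-coding ones, with 107 of 1030 (10.4%) against 227 of 10973 (2.07%). Sharing of reads between overlapping genes does not account for the 2-fold rows in general: 52.99% of them overlap another gene's exons against 52.1% of the other rows, a ratio of 1.02. Most of these 2-fold rows are protein-coding and the non-coding ones were not compared apart, so the ratio does not decide the question for non-coding rows. Few fragments behind non-coding rows stay open, because counting noise at the estimated depth gave 12.4 non-coding rows on average, 11.6% of those observed, and 1.35 protein-coding ones. The simulation set a floor on the length of short transcripts, so it can credit them with too many fragments and understate their noise. AC004079.1, of 102 nt, was credited with 1382 fragments in the TMEM100 library, yet had p = 0.190 in the authors' deposited table.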
